A study of Drosophila melanogaster with 6 samples.

How the data were processed

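RNA from whole Drosophila melanogaster embryos was profiled on 6 Affymetrix arrays, 3 of the Oregon R wild type strain and 3 of age-matched sage mutants. Per the labels' protocols, embryos were kept at 25 degrees, sorted on a COPAS instrument, which sorts large particles in flow, and extracted with TriZol and an RNeasy clean-up. Labelling used a 3′ in vitro transcription kit, which primes at the poly(A) tail, so that probe sets far from the 3′ end depend more on intact RNA. The deposited values are 1 log2 signal per probe set and array. Per the submitters' processing notes the tools were RMA and Partek, with versions not given in the sources used here. RMA corrects background, normalizes by quantiles and returns log2 values by default. The log2 base of the deposited values was taken from this and from their range.

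The deposited table held 18952 rows. 183 control probe sets were kept out of the main test and used only for checks of RNA quality, which left 18769. Gene names came from the platform's annotation table, with symbols updated through the RefSeq table of the Release 6 plus ISO1 MT assembly, in which 11893 of 11982 distinct genes were found. 13647 tested probe sets named 1 gene, 402 named several and 4720 were unnamed here. No gene was named from a probe set with several. 1094 genes had several probe sets. Where 1 probe set stood for a gene, it was the one with the highest mean over the 6 arrays. No coordinates are given, since the files name no genome build, and the RefSeq table served for names, chromosome arms and the order of genes.

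Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment over all 18769, at an adjusted p of 0.05, with a 2-fold threshold as a separate count. Adjusted p-values for single genes are limma's throughout. Nothing in the labels says that replicates were separate collections, so p-values measure only the spread between these samples, which may be technical. 20 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, on 1 probe set per gene. Calls were also adjusted over the list alone. Not every list member had a probe set that named it alone in the annotation used here, and those that did are called measured. For example, 8 of 14 salivary gland regulators, 11 of 15 apoptosis genes and 10 of 16 muscle markers were measured. CrebA, rpr, hid and Mhc were among the genes without such a probe set, so list results cover measured members only. Unnamed probe sets, or those naming several genes, may still carry signal for the others. Positions by chromosome arm were compared by two-sided Fisher's exact tests.

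The genes named were chosen by a rule fixed before the data were examined. It took sage, the 15 largest decreases and 15 largest increases among genes with an adjusted p under 0.05 and groups that did not overlap, and from each list up to 6 members past the threshold, or else the 2 with the smallest p. pip, TrpRS, RFeSP, phu, vvl, cpx, Pgant2, CG12310, Jon44E and the members of 2 gene families were named after their values were seen.

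The steps were tested on simulated data with 200 changed probe sets among 18769. 63% of those shifted by 1 and 89% of those shifted by 2 on the log2 scale were recovered. A list of 8 further probe sets was shifted by −0.8, of which 2 were called, and 5 of the 159 calls were false. camera called the shifted list and no other. The shifted probe sets were those of the salivary gland modifying enzyme and cargo list, and the simulated noise was independent between probe sets. The simulation therefore does not show how camera behaves at the correlation of 0.27 estimated for that list in the data.

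The groups share replicate numbers, given in the sample titles. Deviations from the group means correlated across probe sets at 0.17, 0.28 and 0.31 for arrays with the same number, and between −0.30 and 0.14 for arrays with different numbers. The main fit did not pair the samples by number. A fit with the replicate number as a block was run beside it, and results that change with this block are given.

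Alternatives fixed before the data were examined were quantile normalization, centring on array medians, filters on dim probe sets, other variance models, array weights, the replicate block, 1 probe set per gene, leaving out each array in turn, and other list tests. Alternatives added after the data were seen were the mean 5′ minus 3′ control difference as a covariate, alone and with the block, the regulator list without sage, the gene family tests under each setting, and the choice of fallen probe sets by the fall alone in the check of 5′ signal. The comparison of low signals with the larval glue genes was also chosen after the values were seen. Scan dates and raw array images were not analysed here.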

Results

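Transcript levels were measured in whole Drosophila melanogaster embryos of stages 11 to 16, which span the period when the salivary glands form and mature. Sage is a basic helix-loop-helix transcription factor of the embryonic salivary gland, and the series was made to find its targets. 3 samples were from Oregon R, a standard laboratory wild type strain, and 3 were from sage mutant embryos. Each sample was hybridised to 1 Affymetrix 3′ expression array, and 18769 probe sets were tested on a log2 signal scale. The arrays had a mean signal of 6.8 each and medians between 5.89 and 6.01, and their number limits the precision. Wild type replicate 2 stood apart, with a mean correlation across probe sets of 0.977 to its own group against 0.985 and 0.986 for the other wild type arrays. The mutant arrays lay between 0.989 and 0.993. Control transcripts gave less 5′ signal in the mutants. The mean 5′ minus 3′ difference of 5 control pairs was −1.84 ± 0.08 (SD, n = 3) in wild type and −3.68 ± 0.61 (SD, n = 3) in the mutants, with no overlap between the groups.

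sage itself was lower in every mutant array. Its signal was 8.21, 8.61 and 7.93 in wild type replicates 1 to 3 and 5.28, 5.44 and 5.12 in mutant replicates 1 to 3. The group means were 8.25 ± 0.34 and 5.28 ± 0.16 (SD, n = 3 each). sage (CG12952, chromosome arm 3R) thus fell 7.83-fold, with a log2 change of −2.97 (SE 0.19, limma adjusted p = 0.00125). The nature of the sage lesion is not given in the sources used here, so whether this probe set lies inside the altered sequence is unknown.

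With each gene represented by its brightest probe set, as in the gene lists and chromosome counts, several genes fell by more than sage did. CG13159 fell 56.9-fold, from 14.28 ± 0.32 to 8.45 ± 0.36 (SD, n = 3 each), and Drsl5, a relative of the antifungal peptide Drosomycin, fell 40.2-fold. CG14756 fell 24.1-fold, from 13.58 ± 0.18 to 8.99 ± 0.10. The brightest probe sets of these arrays lay between 14.8 and 14.88. CG18649, EAChm, CG18581, CG34276 and CG8708 had log2 changes of −4.94, −4.92, −4.80, −4.73 and −4.33. CG14453, CG5402 and CG8100 had log2 changes of −4.23, −4.10 and −3.99. ry, which encodes xanthine dehydrogenase, fell 16.7-fold, ATP6AP2, an accessory subunit of the vacuolar proton pump, fell 11.4-fold, and tau, a microtubule-associated protein, fell 9.54-fold. limma adjusted p-values for these 14 genes lay between 6.77e-05 and 0.0195. EAChm did not pass without wild type replicate 1 or mutant replicate 2, nor tau without wild type replicate 1 or 3 or mutant replicate 2 or 3. The control 5′ minus 3′ difference of the mutant arrays had changed by −1.83, which applies to every gene group given here. Any difference in strain background between Oregon R and the mutants is also confounded with loss of sage for every gene, whether lower or higher. Detection above background was not assessed. The mutant means of 11 of the 15 largest decreases, sage included, lay between 3.76 and 5.79, the range of the larval glue genes in wild type, so those folds and their order are not exact. The other 4 were CG13159, Drsl5, CG14756 and ATP6AP2.

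By the brightest probe set of each gene, the largest increase was in CCAP, the crustacean cardioactive neuropeptide, which rose 19.6-fold from 5.37 ± 0.16 to 9.66 ± 0.18 (SD, n = 3 each). A dimmer probe set of RFeSP, the Rieske iron-sulphur protein of respiration, singled out after the values were seen, rose 38.2-fold (limma adjusted p = 0.00016), while the brightest for that gene had a log2 change of 0.25 (limma adjusted p = 0.528). Jon99Fi, a serine protease of the Jonah family, rose 15.8-fold. The odorant-binding protein genes Obp46a and Obp56d rose 8.41-fold and 7.19-fold. pst rose 7.58-fold and the UDP-glycosyltransferase gene Ugt37A2 rose 6.35-fold. The remaining 9 of the 15 were CG14022, CG5697, CG8369, CG12934, CG11370, CG10799, CG5084, CG1894 and CG15202, with log2 changes from 2.52 to 3.13. A dimmer probe set of CG1894 had a log2 change of 0.01 (limma adjusted p = 0.969). limma adjusted p-values for the 15 increases lay between 9.13e-05 and 0.0441. The wild type means of 10 of the 15, CCAP and Jon99Fi included, and that of the dimmer RFeSP probe set (4.93) lay in the range of the glue genes, so those folds are not exact either. With the control 5′ minus 3′ difference as a covariate, chosen after the data were seen, Jon99Fi had a log2 change of 1.97 (SE 0.64) in place of 3.98 (SE 0.37). CG5697, CG15202 and CG1894 did not pass without mutant replicate 2, nor CG1894 without mutant replicate 3. CG8369 and Obp56d passed neither without wild type replicate 1 or 3 nor without mutant replicate 2 or 3. Obp56d also did not pass without wild type replicate 2. Nor did Obp56d pass with all arrays after quantile normalization (limma adjusted p = 0.0552) or with the replicate block (0.0741).

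**Figure D1:**
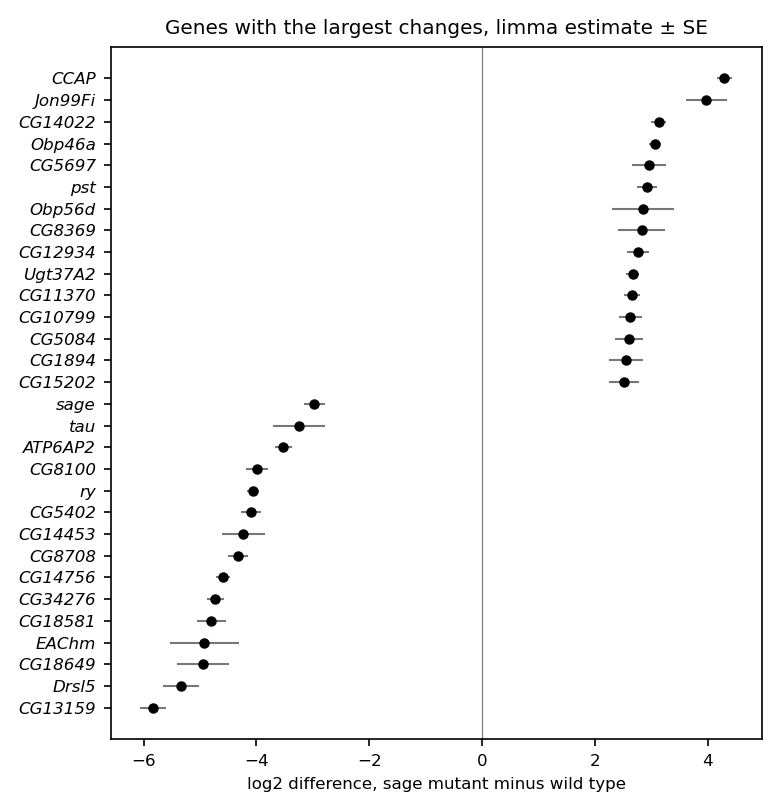
Genes with the largest decreases and increases. The horizontal axis is the log2 difference between sage mutant and wild type embryos (3 arrays each), points are limma estimates and bars are standard errors. The estimates run from −5.83 for CG13159 to 4.30 for CCAP.

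Across the array, 757 probe sets changed at a limma adjusted p under 0.05, 363 lower and 394 higher in the mutants. At least 2-fold changes were found for 397 of them, 185 lower and 212 higher. The 757 probe sets included 678 that name a single gene, and 660 distinct genes had at least 1 changed probe set, bright or dim. After each array was centred on its median, 465 were lower and 334 higher. The groups did not overlap at 4575 probe sets, or 24.4%, against 10% by chance. The count was 1111 without wild type replicate 2, but 212 and 276 without wild type replicates 1 and 3, and 135 and 134 without mutant replicates 2 and 3. It was 956 without mutant replicate 1, the array with the least 5′ control signal, of which 332 were lower and 624 higher.

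Of 9 measured members of the list named salivary gland modifying enzymes and cargo, 4 fell and none rose, and 5 fell when adjusted over the list alone. PH4alphaSG1 and PH4alphaSG2, prolyl 4-hydroxylase subunits of the gland, fell 7.59-fold and 3.64-fold (limma adjusted p = 0.0036 and 0.0371). Papss, which makes the sulphate donor PAPS, fell 2.11-fold (limma adjusted p = 0.00847), and sll, which carries PAPS into the Golgi, fell 2.01-fold (limma adjusted p = 0.0272). The sulphotransferase gene pip had 10 probe sets, of which 6 fell. Its brightest had a log2 change of −0.73 (limma adjusted p = 0.164), and its largest fall, singled out after the values were seen, was 9.05-fold (limma adjusted p = 0.0036). That fold is not exact, because the mutant mean of 5.74 lay in the range of the glue genes.

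The list as a whole was lower by limma's camera test (adjusted p = 0.00751). It had an adjusted p = 0.59 with an estimated correlation, and fry, which asks only whether the members move one way, gave 0.0399. With replicate number as a block, 2 members fell, and PH4alphaSG2 and sll had limma adjusted p-values of 0.0539 and 0.0608. The number that fell was 2 without wild type replicate 1, and 1 without mutant replicate 2 or without mutant replicate 3, in each case including PH4alphaSG1. All these falls were measured on mutant arrays whose control 5′ minus 3′ difference had changed by −1.83.

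**Figure D2:**
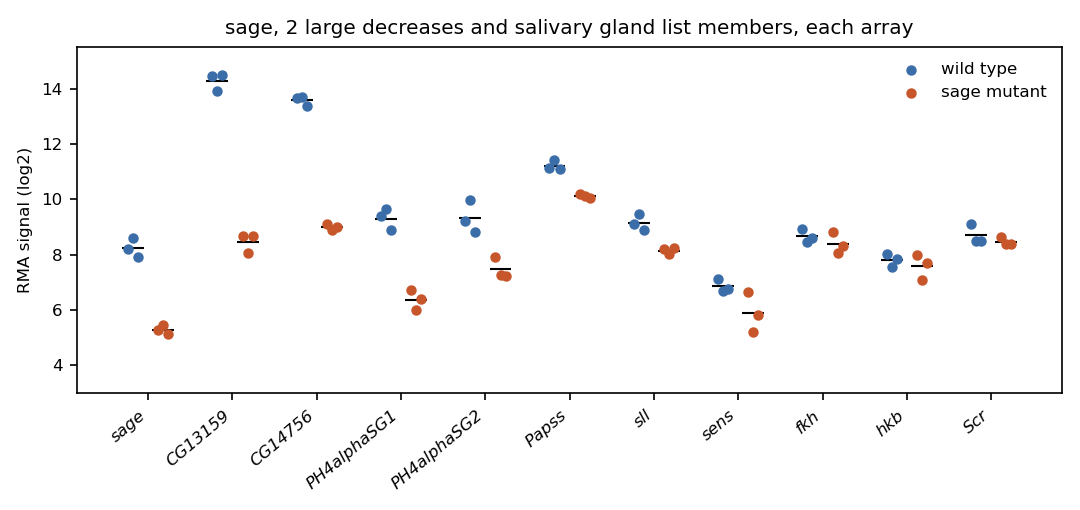
Signal of sage, of CG13159 and CG14756, and of salivary gland list members on each array. The vertical axis is the RMA signal on the log2 scale, points are single arrays (3 wild type, 3 sage mutant) and bars are group means. sage fell from 8.25 to 5.28, while the fkh groups overlapped at means that differed by −0.28.

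Among the salivary gland regulators, 1 of 8 measured members fell, and that was sage. The RNA came from whole embryos, so expression in other tissues could mask a change confined to the gland. The values therefore do not show whether the other regulators changed within it. fkh, a forkhead factor of the gland, had a log2 change of −0.28 (limma adjusted p = 0.591). The zinc finger gene sens had −0.99 and eyg −0.39 (limma adjusted p = 0.2 and 0.207). The list was lower by camera (adjusted p = 0.0325), with an adjusted p = 0.649 with an estimated correlation and 0.135 when sage was left out of the list. It had 0.0522 when probe sets with a mean under 5 were left out, 0.0526 among the brighter probe sets and 0.0952 by fry. camera's adjusted p was 0.103 without wild type replicate 1 and also 0.103 without mutant replicate 2.

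Of the 10 measured salivary gland morphogenesis genes, 1 rose, the integrin subunit gene if (1.70-fold, limma adjusted p = 0.0123), and none fell. Adjusted over the list alone, 1 rose and 1 fell. The larval glue genes, which the gland makes much later, had no changed member among 11 by limma, and none at an unadjusted p under 0.05. camera gave adjusted p-values of 0.507 and 0.68 for these lists. if did not pass the test without wild type replicate 1 or 3 or without mutant replicate 2 or 3, when no member of its list rose.

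Of 10 prolyl 4-hydroxylases and partners, the 2 that fell were PH4alphaSG1 and PH4alphaSG2 (camera adjusted p = 0.0997). Of 30 secretory pathway components, Srp68 and Srp54k, both proteins of the signal recognition particle, fell 1.72-fold and 1.64-fold (camera adjusted p = 0.101). Of 10 mucin-type glycosylation genes, the N-acetylgalactosaminyltransferases Pgant6 and Pgant8 fell 1.91-fold and 1.5-fold (camera adjusted p = 0.127, fry adjusted p = 0.0399). A dimmer probe set of Pgant2 also fell (log2 change −0.44, limma adjusted p = 0.0455), beside −0.04 at its brightest. None of 12 endoplasmic reticulum stress and folding genes passed limma, with 3 at an unadjusted p under 0.05. Atf6 and crc had log2 changes of −0.85 and −0.43 and fell when adjusted over the list alone (camera adjusted p = 0.052). With the replicate block, that list had a camera adjusted p = 0.0419 and Atf6 a limma adjusted p = 0.0469, while PH4alphaSG2, Srp68 and Pgant8 passed no longer. Of 11 apoptosis genes, the pro-apoptotic gene skl fell 2.25-fold and none rose, against 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.306). Srp68, Srp54k, Pgant8 and skl lost their calls without wild type replicate 1 or 3 and without mutant replicate 2 or 3, and Pgant6 without mutant replicate 2 or 3. Srp54k and Pgant8 were also lost without mutant replicate 1, and Pgant8 without wild type replicate 2. Among the brighter probe sets and with trend and robust variance, Srp54k had limma adjusted p-values of 0.0589 and 0.0553 and Pgant8 0.0781 and 0.104, and Pgant8 had 0.0515 with a mean of at least 5. Without wild type replicate 3, camera gave adjusted p-values of 0.0311 for the endoplasmic reticulum list, 0.00526 for the secretory pathway list and 0.0311 for the prolyl 4-hydroxylase list. Without mutant replicate 1 it gave 0.0114 for the endoplasmic reticulum list, and Atf6 passed limma (0.018). Atf6 also passed after centring (0.0475) and crc after quantile normalization (0.0498). With array weights the endoplasmic reticulum list passed camera (0.0218) and Atf6 and crc passed limma (0.00967 and 0.02), and the list also passed with the mean of all probe sets of a gene (0.0342). On the mutant arrays of these groups too the control 5′ minus 3′ difference had changed by −1.83.

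Few markers of other embryonic tissues passed the test. Of 8 midgut markers, the trypsin gene alphaTry rose 2.72-fold and none fell, with 3 higher adjusted over the list alone (camera adjusted p = 0.052). Of 10 muscle markers, Mp20 rose 2.30-fold (camera adjusted p = 0.0817). Of 14 hemocyte and fat body markers, Pxn, a peroxidasin, fell 1.71-fold and the phagocytosis receptor gene NimC1 rose 1.67-fold (camera adjusted p = 0.541). Only 1 of 2 probe sets of Pxn passed limma. None of 12 nervous system markers passed limma by its brightest probe set, with 5 at an unadjusted p under 0.05. repo and pros had log2 changes of −0.94 and −0.86, and 2 were lower and 2 higher adjusted over the list alone (camera adjusted p = 0.848). A dimmer probe set of cpx rose 2.30-fold (limma adjusted p = 0.0305), beside a log2 change of 0.14 at its brightest. repo had a limma adjusted p of 0.0521 and passed after centring (0.0413), with a mean of at least 5 (0.0452), among the brighter probe sets (0.047), with trend and robust variance (0.0365), with array weights (0.00822), with 1 probe set per gene (0.0465) and without wild type replicate 2 (0.0426). With the replicate block pros passed (limma adjusted p = 0.0373) and alphaTry did not (0.0595), and with array weights pros passed too (0.0123). With the control 5′ minus 3′ difference as a covariate, alphaTry had a log2 change of 0.06 (SE 0.36) in place of 1.44 (SE 0.24), and Pxn −0.28 (SE 0.29) in place of −0.77 (SE 0.12). Mp20, Pxn and NimC1 lost their calls without wild type replicate 1 or 3 and without mutant replicate 2 or 3, and alphaTry without wild type replicate 1 or 3 or mutant replicate 2. NimC1 was also lost without mutant replicate 1, after quantile normalization or centring and among the brighter probe sets (limma adjusted p = 0.0596). The midgut list passed camera after centring (adjusted p = 0.0376), with the mean of all probe sets of a gene (0.0481) and without wild type replicate 1 (0.034), wild type replicate 3 (0.0311), mutant replicate 1 (0.025) or mutant replicate 3 (0.0127). The muscle list passed after centring (0.0464) and without wild type replicate 1 (0.0311), wild type replicate 3 (0.0223) or mutant replicate 1 (0.0446).

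None of 10 trachea markers and 14 epidermis and cuticle markers passed limma by its brightest probe set, with 1 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.68 and 0.888). In trachea, serp and pio had log2 changes of 0.37 and 0.34. A dimmer probe set of vvl fell 2.52-fold (limma adjusted p = 0.0458), beside a log2 change of −0.13 at its brightest. In epidermis, Ddc and ple, enzymes that make the dopamine used in cuticle, had 1.53 and 0.32, the median of the list was −0.05, its mean 0.10 and camera's direction up. Ddc passed limma without mutant replicate 1 (adjusted p = 0.0147), and Ddc and ple passed with array weights (0.037 and 0.0271). None of 11 maternal and germ line markers and 10 early segmentation genes passed, with 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.541 and 0.8). osk and exu had log2 changes of 1.27 and 0.47, and Kr and hry −0.48 and 0.44. osk passed limma with array weights (adjusted p = 0.0397), and the maternal list passed camera without wild type replicate 3 (adjusted p = 0.0311).

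Of 12 measured detoxification genes, 3 rose and none fell, and 6 rose and 1 fell when adjusted over the list alone. The 3 were glutathione S-transferase genes, GstE2 at 3.79-fold, GstE1 at 2.81-fold and GstD2 at 2.28-fold (limma adjusted p = 0.0256, 0.0135 and 0.0427). The list was higher by camera (adjusted p = 0.021), with an adjusted p = 0.59 with an estimated correlation and 0.0399 by fry. It had 0.0538 when probe sets with a mean under 5 were left out and 0.0751 among the brighter probe sets, and no member passed limma without mutant replicate 2 or without mutant replicate 3. Without wild type replicate 1, 1 member rose, and without wild type replicate 3 or mutant replicate 1, or after quantile normalization, 2 did. These rises too were measured on arrays whose control 5′ minus 3′ difference had changed by −1.83.

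None of 5 measured heat shock genes (of 13 listed) and 6 measured antimicrobial peptide genes (of 14 listed) passed limma. Of these, 1 and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.429 and 0.68). Hsp83 and the Hsp70 genes were among those with no probe set that named them alone. Hsp26 and stv had log2 changes of 0.99 and 0.80, and Mtk and Def −0.37 and −0.13. Among the lists not given a count adjusted over the list alone, it equalled the count over all probe sets. camera called 3 of the 20 lists and none with an estimated correlation.

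**Figure D3:**
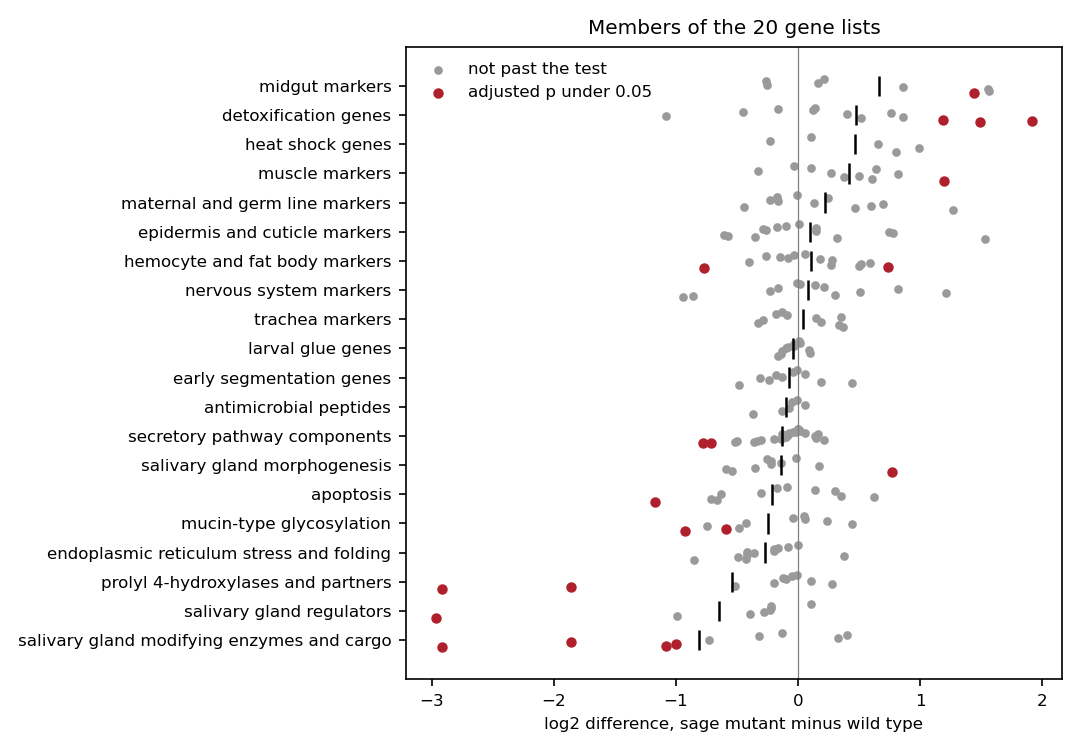
Members of the 20 gene lists. The horizontal axis is the log2 difference between sage mutant and wild type embryos, each point is 1 gene by its brightest probe set, red points passed a limma adjusted p under 0.05 and vertical bars are list means. PH4alphaSG1 and PH4alphaSG2 appear in 2 lists, and the lowest list mean is −0.81 for the salivary gland modifying enzymes and cargo.

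**Figure D4:**
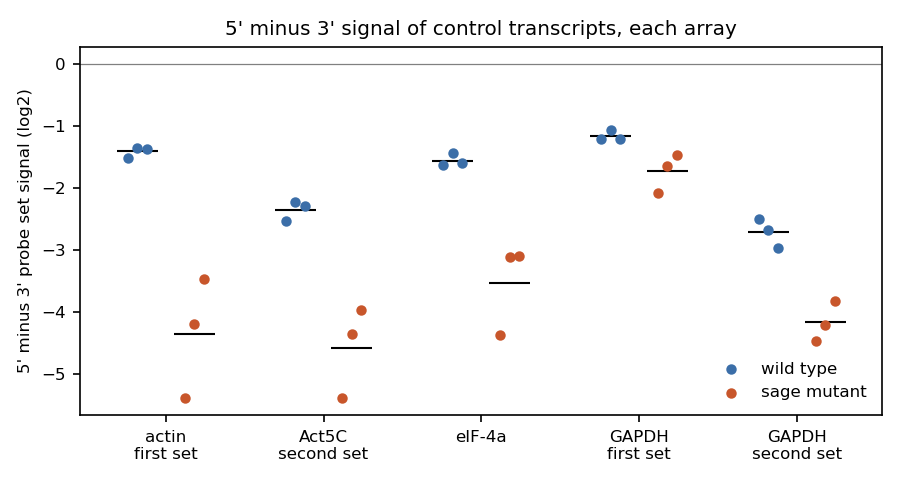
5′ minus 3′ signal of control transcripts on each array. The vertical axis is the log2 difference between the 5′ and 3′ probe sets of 5 control pairs, points are single arrays (3 wild type, 3 sage mutant) and bars are group means. Every mutant array lies below every wild type array for each pair, with means of −1.42 and −4.36 for the first actin set.

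The positions of changed genes were compared because a mutant chromosome can carry linked sequence that differs from the wild type strain. Genes on X were called less often than genes elsewhere, 70 of 1873 or 3.74% against 5.26% (odds ratio 0.70, 95% interval 0.53 to 0.90, Fisher's exact test, adjusted p = 0.0283 over 6 arms). On 3R, where sage lies, 161 of 2974 genes were called (odds ratio 1.11, adjusted p = 0.318), and on 3L the odds ratio was 1.25 (adjusted p = 0.0798). 3L passed after centring (adjusted p = 0.0232), with a mean of at least 5 (0.00812), among the brighter probe sets (0.0165), with trend and robust variance (0.0048), with array weights (0.035) and without mutant replicate 1 (0.00517), at odds ratios from 1.16 to 1.37. Its odds ratio was 0.98 with the replicate block and 0.92 and 0.96 without mutant replicates 2 and 3. When only changes of at least 2-fold were counted, the odds ratio on 3L was 1.07 (adjusted p = 0.797). By that count it was 1.3 on 3R (95% interval 1 to 1.67, adjusted p = 0.117) and 0.53 on X (adjusted p = 0.00382). With the replicate block the odds ratio on X was 0.78 (adjusted p = 0.378), and without mutant replicate 2 it was 0.48 (adjusted p = 0.198). Within 25 genes of sage on either side, 2 of 50 were called, ATP6AP2, which adjoins sage, and phu. That share was 4% (95% exact binomial interval 0.49% to 13.71%) against 4.89% of 8914 genes on the other chromosome arms.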

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

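The tests of 5′ signal loss were chosen only after the result was seen. The counts over other splits of the arrays were planned.

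Control probe sets, which the comparisons leave out, differed between the groups. 46 of 183 passed a limma adjusted p under 0.05, and the mean 5′ minus 3′ difference of 5 pairs changed by −1.83 (3.6-fold, two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The difference was −1.88, −1.76 and −1.89 in wild type replicates 1 to 3 and −4.35, −3.51 and −3.17 in mutant replicates 1 to 3. For the first actin set it changed by −2.94, for eIF-4a by −1.97 and for the first GAPDH set by −0.57. The 3′ ends changed less, by −0.33 for actin and −0.19 for eIF-4a. Hybridization controls were also lower in the mutants, BioB by −0.89 at its 3′ end and CreX by −0.56.

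Shorter RNA or less complete labelling could lower probe sets far from the 3′ end, and mutant replicate 1, with the least 5′ signal, would then lie below replicates 2 and 3, as in the controls, where this gap was 0.55 of the fall. For 8 fallen salivary gland and pip probe sets, 4 of them of pip, the median was −0.30 (95% bootstrap interval −0.44 to −0.11), replicate 1 lay above the others in all 8, and with 1 value for each of their 5 genes the median was −0.17 (−0.42 to −0.07). For 120 other probe sets that fell at least 2-fold and stayed above 6 in the mutants it was −0.12 (−0.17 to −0.07), with 15 at 0.5 or more of the control value, and when probe sets were chosen by the fall without a p-value, which favours arrays that lie close together, the medians were −0.31 over 9 and −0.16 over 154. With the control difference as a covariate the median changes went from −1.80 to −3.08 and from −1.37 to −1.58, and no call was left because the covariate correlated with genotype at −0.93 and widened the median SE from 0.24 to 0.59 and from 0.18 to 0.47 (7 of 8 and 80 of 120 at an unadjusted limma p under 0.05). The gap thus did not follow the controls, but it rests on a single array and probe positions were not used here, so loss of 5′ signal and genotype cannot be told apart for these falls.

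6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 757 changed probe sets and 397 with a 2-fold change, and the highest other split gave 0 for both, so that 1 of 10 splits reached each real count. The other 3 splits that part all 3 numbered pairs also gave 0.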

How the results depend on the processing

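The fits with the 5′ minus 3′ control difference and the regulator list without sage were chosen after the result was seen. sage kept its direction and call in every planned setting, with log2 changes from −3.13 to −2.79 when single arrays were left out. Quantile normalization gave 719 changed probe sets, the filter at a mean of 5 737, the brighter probe sets 562, trend and robust variance 999, and the replicate block 641, of which 509 were among the 757. The block changed the calls given beside the results, Obp56d (limma adjusted p = 0.0741) and no other call of a named gene or list. Without variance moderation, 67 probe sets changed (37 lower, 30 higher), 44 of them 2-fold (24 lower, 20 higher), with 2968 at an unadjusted p under 0.05. Array weights, which gave wild type replicate 2 a weight of 0.27, called 2737 (1230 lower, 1507 higher), 643 of them 2-fold with 400 higher. With single arrays left out, the counts ranged from 134 to 1111 in all, 62 to 507 lower and 69 to 624 higher, and for 2-fold changes from 128 to 594, 60 to 218 lower and 68 to 400 higher. Of 49 named genes with a call, 18 kept it without moderation and 26 to 47 with an array left out. With the control difference as a covariate, 0 probe sets changed by limma in either direction or 2-fold (1613 at an unadjusted p under 0.05), and sage had −2.97 (adjusted p = 0.275). With the block added it was 0 again (649), and sage had −2.84 (adjusted p = 0.999); no chromosome test could be made from 0 calls. In these fits hry reversed to −0.19 and −0.24, stv to −0.69 and −0.55, Hsp26 to −2.38 and −2.43, and the heat shock list, by camera, was lower with adjusted p = 0.00104 and 0.00979, as was the endoplasmic reticulum list with the same 2 values. The detoxification list lost its camera call (0.387 and 0.882), and with the block the modifying enzyme list had 0.0612 and the muscle list was higher (0.00979). alphaTry went from 1.44 to 0.06 and, in the fit with the block, reversed to −0.35. Under the covariate alone, the change was less than 0.5 of its first value in 1 of 27 named genes that fell (Pxn) and 2 of 23 that rose (alphaTry and Jon99Fi). Mtk went from −0.66 to 0.02 with single arrays left out and reversed only without wild type replicate 2. Lists called by camera were 5 after centring, 1 with a mean of at least 5, 1 among the brighter probe sets, 5 with the mean of all probe sets of a gene, 0 with an estimated correlation, and 2 to 9 with single arrays left out, 9 without wild type replicate 3 and 6 without mutant replicate 1. The odds ratio on X was 0.78 with the replicate block (adjusted p = 0.378) and 0.32 to 0.70 with single arrays left out, and on 3R 0.97 to 1.5. Of the single-gene values over all settings, 874 kept their direction and side of the threshold, 222 were weaker, 20 stronger and 8 reversed. These counts include the 2 covariate fits, chosen after the data were seen, in which no call was kept. They also include genes called neither in the main fit nor in the other setting. Apart from the wider errors under the covariate and the fewer arrays, the cause was not tested. Signal over background on these arrays was not used here, so dim probe sets have no lower bound.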

Other observations

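The tests of the genes next to sage, the split of chromosome arms by direction and the gene family values under other settings were chosen only after the result was seen.

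A larger share of genes rose in the Jonah family of digestive proteases than among other genes. 6 of 13 measured Jonah genes passed the limma threshold as higher, 46.2% against 2.8% of other genes (Fisher's exact test, adjusted p = 8.37e-05). Besides Jon99Fi they were Jon25Biii (4.86-fold), Jon25Bii (4-fold), Jon25Bi (3.45-fold), Jon99Ci (3.10-fold) and Jon74E (2.30-fold), while Jon44E fell. The count was 5 after quantile normalization or centring and 5 with the replicate block, but 2 without wild type replicate 1, 3 without wild type replicate 3, 2 without mutant replicate 2 and 0 without variance moderation. Near copies within the family can share probes, so single members are uncertain. Fisher's test counts members as independent, so shared probes or joint expression can make its p-value too small. With the control 5′ minus 3′ difference as a covariate the median log2 change of the 6 went from 1.89 to 0.53, that of Jon99Fi from 3.98 to 1.97 (SE 0.64), and 5 of the 6 had less than 0.5 of their change, against 3 of 50 named genes with a call, Jon99Fi among them. The midgut trypsin gene alphaTry, which also rose, went from 1.44 to 0.06 (SE 0.36). The wild type control differences lay close together (−1.88, −1.76 and −1.89). The covariate thus rests mostly on mutant replicate 1 (−4.35) against replicates 2 and 3 (−3.51 and −3.17). Named genes were mostly picked for a small p or groups that did not overlap, which favours arrays that lie close together. The contrast with them therefore does not show that the Jonah rises follow RNA quality, and the measure and genotype are confounded.

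Among glutathione S-transferases of the epsilon class, which conjugate glutathione to foreign and oxidised compounds, 4 of 13 measured members rose and 9 did not pass the test. They were GstE1, GstE2, GstE7 (2.10-fold) and GstE9 (2.62-fold), 30.8% against 2.8% of other genes (Fisher's exact test, adjusted p = 0.0208), and 2 of these were in the fixed detoxification list. The count was 7 without wild type replicate 2, 2 without wild type replicate 3, 1 without wild type replicate 1 and 0 without mutant replicate 2 or 3 or without variance moderation. Jonah and GstE were the 2 results past the threshold among 106 tests of 53 families defined by symbol, and the prediction was fixed before the test. Both p-values count family members as independent. No family passed by the fit with the control difference as a covariate, which called no probe set.

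Both genes adjacent to sage had a probe set at least 2-fold lower. ATP6AP2 had a log2 change of −3.52, and TrpRS, the tryptophanyl-tRNA synthetase gene, had 1 probe set at −2.06 (limma adjusted p = 0.00189) beside others at −0.20 and 0.04. Such a probe set was found in 2 of 2 adjacent genes, in 0 of 48 genes 2 to 25 places away and in 1.24% of all genes. A lesion or linked sequence that extends from sage into its neighbours may account for both, but these genes were picked because they were low, so the counts do not decide it. The gap of mutant replicate 1 below the others was 0.03 of the fall for ATP6AP2 and −0.02 for TrpRS, against 0.55 in the controls. With the control difference as a covariate the log2 changes were −3.12 and −2.02. These values rest mostly on 1 array, and the TrpRS probe set was dim in the mutants (mean 4.47). Loss of 5′ signal in the mutant arrays thus stays open, and regulation by Sage stays open and untested.

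The genes that fell were unevenly spread, with an odds ratio of 1.82 (95% interval 1.37 to 2.40) on 3L and 0.38 on X (Fisher's exact test, adjusted p = 0.000116 for both). The 3L value was 1.58 with the replicate block (unadjusted p = 0.00452) and, from 13 and 12 genes, 1.66 and 1.58 without mutant replicates 2 and 3 (unadjusted p = 0.132 and 0.18). If sequence differences between the strains' chromosomes 3 made the calls, genes with 1 changed and 1 steady probe set could lie there more often, but the odds ratio was 1.19 (95% interval 0.57 to 2.48, Fisher's exact p = 0.61). Fallen genes adjoined each other on 3L in 6 pairs against a mean of 2.5 in 10000 shuffles (permutation p = 0.037), among them CG18581, CG12310, CG18649 and EAChm, but the odds ratio stayed at 1.78 (95% interval 1.32 to 2.37) with each run counted once. Runs therefore do not account for the excess on 3L, while a sequence difference between the strains stays open because its interval is wide. That test also takes the other chromosomes as alike between the strains, which is not known here. Such genes made up 3.5% on chromosome 3 and 3% elsewhere.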
